A study of Mus musculus with 8 samples.

How the data were processed

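The series holds bulk RNA sequencing of 8 libraries of mouse OT-I CD8 T cells, whose T cell receptor recognises the ovalbumin peptide SIINFEKL. Per the labels' protocols, cells activated with that peptide were kept with IL-2 for 5 days in RPMI medium with 10% fetal bovine serum, without or with 470 µM o-phosphoethanolamine (pEtn), the phosphorylated headgroup precursor of phosphatidylethanolamine. Cells were sorted into lysis buffer and cDNA was made with a SmartSeq kit and 15 amplification cycles, per the labels' protocols. The labels give 4 numbered libraries of each medium. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here, so overlapping or antisense genes and near-identical copies could share reads. The symbols in the deposited table are partly older ones (Ept1 is the present Selenoi), and no coordinates are printed.

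The table deposited by the authors gives, for 45232 genes, the total count of each library, which is a whole number and was used for every main test. It also holds RPKM and TPM values deposited by the authors, which entered alternatives only. A further column of each library, named CPM by the authors and treated here as a signal, equals CPM (counts scaled by the library total) times 1 constant per library and entered no test. No row lacked a gene name. The 24 rows of mitochondrial ribosomal and transfer RNA were at 0 in every library. Of the gene identifiers, 44585 (98.6%) matched GENCODE release M21, which was used only for transcript length and GC content. Total counts ran from 29223765 to 35504571 per library and genes with a count from 14318 to 15205. Intervals from such counts would cover counting error only, since the reads carry no molecular identifiers.

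Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 11862 of the 17625 genes with any count, library sizes were scaled by TMM, and the medium was tested with the robust quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are CPM after TMM scaling, as mean ± SD over the 4 libraries of a medium. Before the data were examined, 37 gene lists were fixed, 29 of them on T cell biology and metabolism, 2 on RNA quality or handling stress and 6 on other cell types. Lists with at least 5 tested members (30 lists) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, then with an estimated correlation and with fry. A list's median is that of its members' edgeR log2 fold changes. Overlap of lists with called genes was tested with Fisher's exact test against all genes tested, one-sided.

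The genes named follow a rule fixed before the data were examined. It takes, in each direction, the 10 called genes with the largest log2 fold change. Only genes with a mean of at least 5 CPM and no overlap between the media qualify. Unnamed clones, pseudogenes and receptor segments were left out by their symbols, which did not catch the receptor constant gene Tcrg-C4. The rule adds the up to 4 members with the smallest p of each biology list that was called or held a called gene. It also adds 16 genes named whatever their values. Some genes that the rule names are not reported here. Genes named outside the rule are stated as chosen after their values were seen.

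The replicate numbers of the labels are shared by both media. Deviations of the libraries from their group means correlated between same-numbered libraries at 0.57, 0.55, 0.44 and 0.45 across 11862 genes, all above the 0.1 set for pairing, so the numbers were taken to pair the libraries. The highest correlation between different numbers across media was 0.41, close to pairs 3 and 4. The best match of all 8 libraries in the other medium was their own number, and of 6 of the 8 among all libraries. The pairing thus comes from the data and the shared numbers, and the labels do not say what a number stands for. The test without the number as a block was the one fixed beforehand. Blocked values are given where they change a call or move a count by over 1.5 times, and for some genes that lost calls when a library was left out. Replicates 3 and 4 of each medium were much closer to each other than other pairs of the same medium. The chi-square per gene of their counts was 11.2 in RPMI and 5.04 in pEtn, against 51.1 to 107 for the other same-medium pairs, over genes with at least 20 counts in a pair. These values exceed the counting noise of independent reads, but amplified reads are not independent, so they do not show that replicates 3 and 4 are separate samples. They were kept as separate libraries because the labels number them so, and were summed as an alternative. Nothing in the labels says that the numbered libraries came from separate cultures or mice, so p-values measure only the spread between these libraries, which may be technical.

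On simulated counts for the same design (11862 genes), 73% of 100 genes changed 2-fold and 26% of 100 changed 1.5-fold were recovered, and 5.71% of the calls were false. Of 20 simulated lists of 20 genes, the 1 shifted by 0.5 on the log2 scale was called and 0 of the others. These simulated genes vary independently of each other, unlike real ones. The simulated libraries are independent too, without the pairing by number or the closeness of replicates 3 and 4. The shares recovered and false thus may not hold for the real libraries. Alternatives fixed beforehand were other scalings and filters, the replicate block, DESeq2 1.42.0, limma-voom with and without library quality weights, limma on log2(TPM + 1) and log2(RPKM + 1), a fold change minimum of 2, the other list tests and leaving out each library. Alternatives added after seeing the data were replicates 3 and 4 summed, fits on some replicate numbers only, fry with the block, and offsets for GC content and transcript length (splines with 5 degrees of freedom, 99.7% of tested genes with a value). Single library measures were compared with two-sided exact permutation tests over 70 assignments, whose smallest possible p is 0.0286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.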

Results

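RNA was sequenced from 4 libraries of activated OT-I CD8 T cells kept in RPMI medium and 4 kept in the same medium with 470 µM pEtn for 5 days. Total counts ran from 31280997 to 34474420 per library in RPMI and from 29223765 to 35504571 with pEtn. The comparison asks what adding pEtn, a metabolite of the ethanolamine branch of phospholipid synthesis, does to the transcripts of these cells. The series title places the question among media modelled on the fluid of tumours.

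With pEtn the cells held more RNA of the granzymes Gzma and Gzmk, the crosslinking enzyme Tgm2 and the collagen-binding integrin Itga1, and less of the peptide transporter Slc15a1, the transcription factor Zfp683 and granzyme Gzmc. Genes of ribosomal proteins, serine, one-carbon and purine synthesis, IL-2 signalling and early T cell activation were lower, while mitotic genes were higher. For these lists the smallest adjusted p was 0.405 with an estimated correlation. Gzma went from 2145 ± 304 to 6280.3 ± 1460 CPM (SD, n = 4) and Slc15a1 from 9.93 ± 2.86 to 0.496 ± 0.301 CPM (SD, n = 4). Cd8a stood at 316 ± 40.3 and 339 ± 65.8 CPM and Gzmb, the most abundant granzyme named here, at 10481 ± 1452 and 9504 ± 2221 CPM (SD, n = 4), with edgeR adjusted p of 0.711 and 0.619.

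In all, 1516 of 11862 genes were called by edgeR, 619 higher and 897 lower with pEtn, and 369 of them changed at least 2-fold (109 higher, 260 lower). In 2416 of the 11862 genes tested the media did not overlap. Chance gives this for 2.86% of genes if all libraries are independent and exchangeable. The pairing by number and the closeness of replicates 3 and 4 go against that, so this share is not a sound reference here. With the replicate number as a block 3830 genes were called, 1871 higher and 1959 lower, including 1509 of the 1516. The count depended on single libraries and on replicates 3 and 4, which resembled each other in both media: it was 796 without RPMI replicate 3, 861 without RPMI replicate 4, 997, 941 and 817 without pEtn replicates 1, 3 and 4, and 325 (79 higher, 246 lower) with replicates 3 and 4 summed into 1 library. Replicates 1 and 2 alone gave 32 genes and replicates 3 and 4 alone 5675. Of 98 named called genes, 54 lost the call with replicates 3 and 4 summed, and these losses are not marked gene by gene below. The leave-one-out fits named below had no block and break a pair, so a lost call may reflect spread between replicate numbers. With the block on all libraries 4 of the 98 lost the call, and 8 with the block and replicates 3 and 4 summed.

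**Figure D1:**
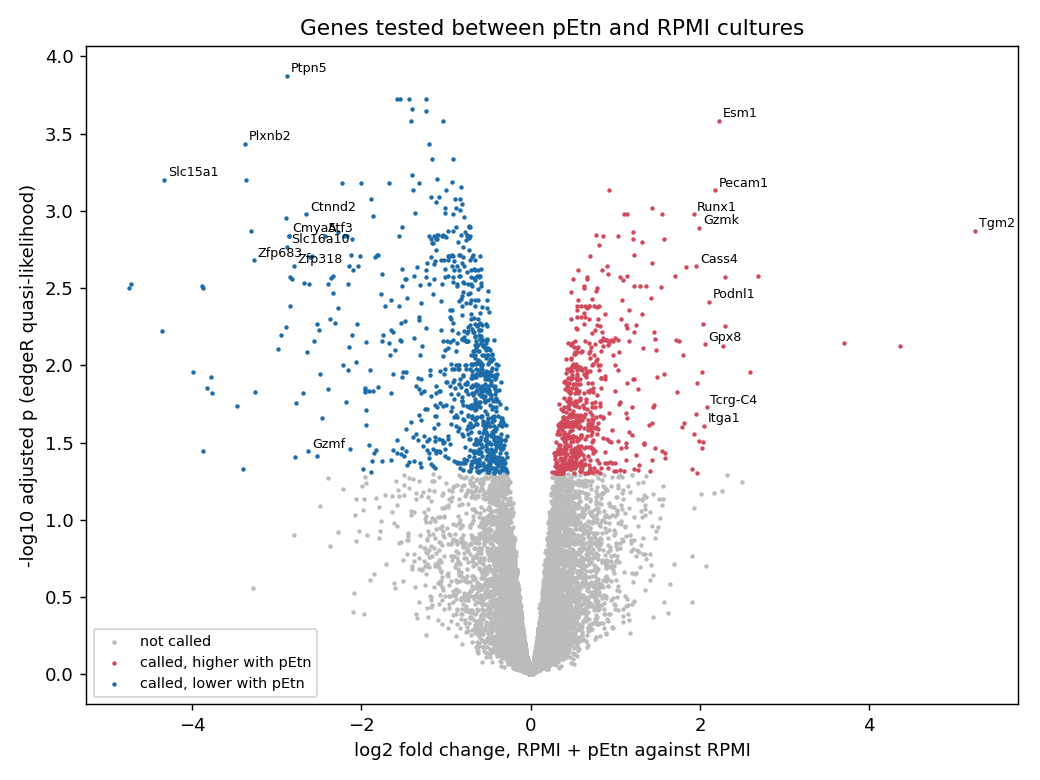
Each point is 1 of 11862 genes, with the log2 fold change of pEtn against RPMI on the x axis and the negative log10 of the edgeR adjusted p on the y axis. Red points (619) were called higher and blue points (897) lower with pEtn, and the labelled genes are the 10 with the largest change in each direction under the naming rule.

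Among the largest changes, Tgm2 (ENSMUSG00000037820) rose by 5.26 on the log2 scale (SE 0.60, adjusted p = 0.00134), from 1.56 ± 1.22 to 60.3 ± 33.8 CPM (SD, n = 4). Esm1, a secreted proteoglycan, rose 4.69-fold and Pecam1, an adhesion molecule, 4.54-fold (adjusted p = 0.000261 and 0.000734). Podnl1, Gpx8, Gzmk, Cass4 and the transcription factor Runx1 rose 4.30-, 4.17-, 3.98-, 3.88- and 3.80-fold. Tcrg-C4, a gamma receptor constant gene with close copies whose reads may be shared, rose 4.23-fold and Itga1 4.14-fold, and the calls were lost in 2 and 4 leave-one-out fits (highest adjusted p 0.0616 and 0.0739, without RPMI replicate 3). Slc15a1 fell by 4.33 on the log2 scale (SE 0.40, adjusted p = 0.000628). The semaphorin receptor Plxnb2 was 10.4-fold lower, Zfp683 9.66-fold, the aromatic amino acid transporter Slc16a10 7.36-fold and the phosphatase Ptpn5 7.34-fold lower, each in 4 of 4 replicate numbers. Cmya5, Zfp318, Ctnnd2 and the stress-induced transcription factor Atf3 were 7.25-, 6.98-, 6.27- and 5.41-fold lower (adjusted p from 0.00105 to 0.00228). Gzmf was 6.19-fold lower (adjusted p = 0.0359) and lost its call in 6 leave-one-out fits, with the highest adjusted p of 0.0946 without pEtn replicate 1.

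**Figure D2:**
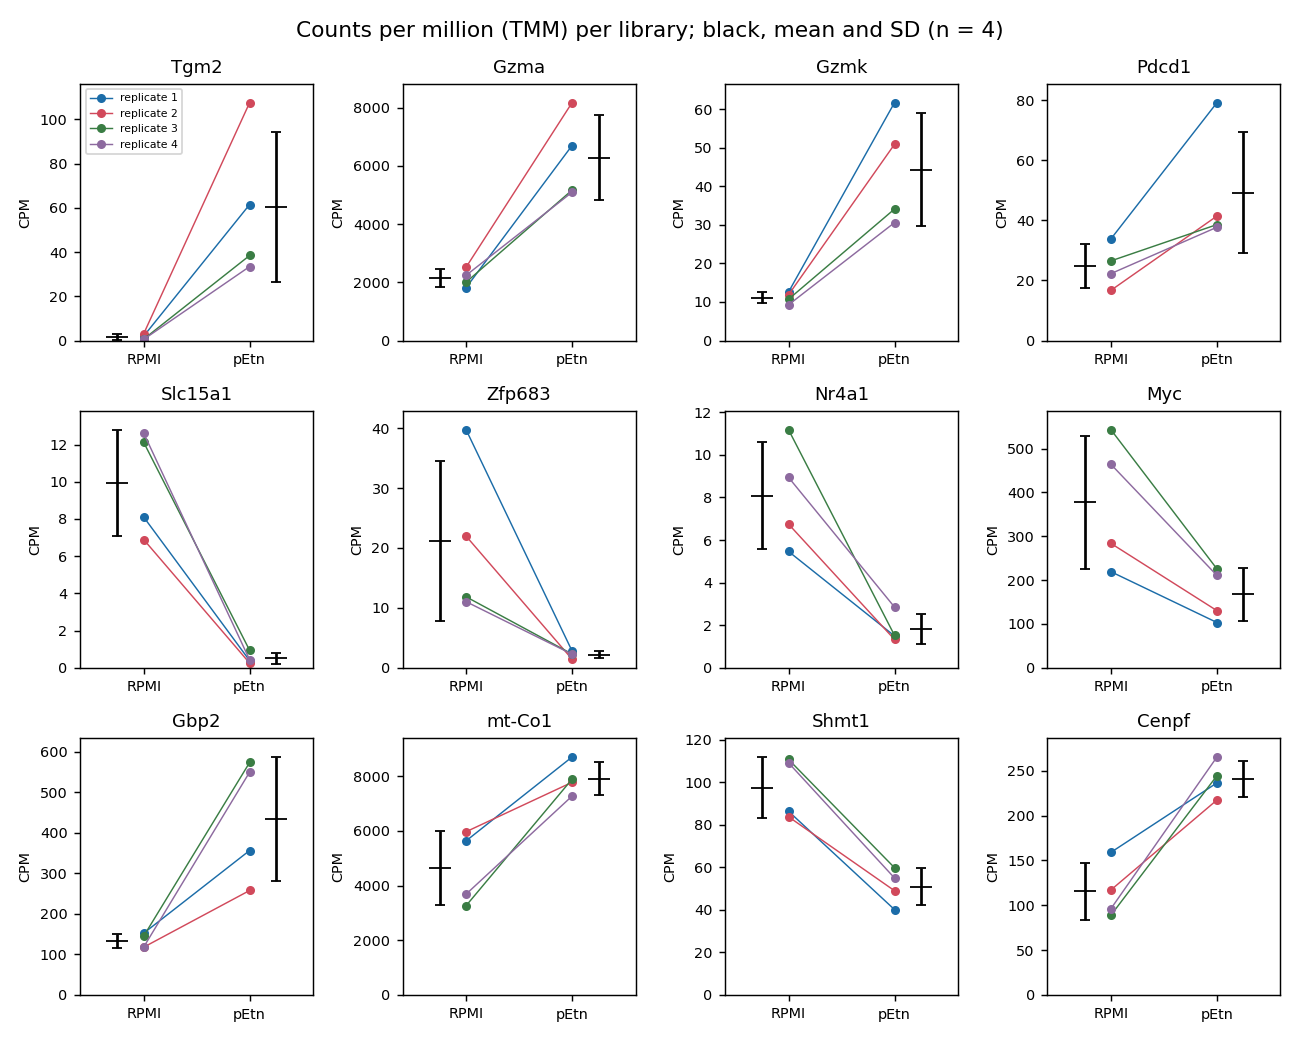
Each panel shows 1 gene in CPM (y axis, from 0) in RPMI and pEtn, with points for libraries, lines joining libraries of the same replicate number, and black bars for mean ± SD (n = 4). All 12 genes were called by edgeR, and in Myc, Zfp683 and mt-Co1 the RPMI libraries spread widely, as in Myc at 377 ± 151 CPM.

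Effector genes moved in both directions. Of 17 cytotoxic granule and death ligand genes, 2 rose (Gzma by 1.55 and Gzmk by 1.99 on the log2 scale) and 3 fell, among them Gzmc at -2.39 and the lysosomal membrane gene Lamp1 at -0.52, with the same counts adjusted over the list alone and a camera adjusted p of 0.601. Gzmb, Gzmc and Gzmf belong to 1 cluster of similar genes whose reads may be shared. Prf1, encoding perforin, stood at 155 ± 102 and 299 ± 310 CPM (SD, n = 4, edgeR adjusted p = 0.407). Of 16 cytokine and chemokine genes 4 fell and 0 rose, 6 and 1 adjusted over the list alone and 7 and 2 with the replicate block. The list fell with a median of -0.63 (camera adjusted p = 0.0299), with adjusted p = 0.405 with an estimated correlation. Its falling members included Csf2 at -2.78, Xcl1 at -1.13, Lta at -1.29 and Ccl4 at -2.53, the last pair losing the call with the block (adjusted p = 0.0579 and 0.0916). Ifng, encoding interferon gamma, stood at 3.85 ± 2.11 and 9.88 ± 3.43 CPM (SD, n = 4), with an edgeR adjusted p of 0.0711 and 0.0239 with the block. With a filter of 5 CPM in 4 libraries the cytokine list had an adjusted p of 0.446. Without RPMI replicate 2 or 3 it had an adjusted p of 0.0506 and 0.0711, and Ccl4 and Xcl1 lost their calls in 6 and 7 leave-one-out fits (highest adjusted p 0.108 without RPMI replicate 3 and 0.118 without pEtn replicate 3).

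Genes switched on by the T cell receptor were lower. Of 22 such transcription factors and early genes 4 fell and 1 rose, 5 and 1 adjusted over the list alone and 10 and 2 with the block. The list fell with a median of -0.36 (camera adjusted p = 0.0237), with adjusted p = 0.405 with an estimated correlation. Batf3 fell by 2.28, Nr4a1 by 2.16, Egr2 by 1.53 and Myc by 1.17 on the log2 scale. With a filter of 5 CPM in 4 libraries the median, on the log2 CPM scale of camera, went from -0.38 to -0.25 and the adjusted p to 0.194. The list also lost its call without RPMI replicate 3 (0.0711) or pEtn replicate 1 (0.0512), Egr2 in 7 leave-one-out fits (highest adjusted p 0.110 without RPMI replicate 3) and Myc in 5 (0.121 without RPMI replicate 3). Among 22 receptor signalling components 3 rose and 3 fell, also adjusted over the list alone, and 5 and 4 with the block (camera adjusted p = 0.547): Malt1 at -0.91 was among the lower, and Rasgrp1 at 0.59 and Plcg1 at 0.57 among the higher. Plcg1, the phospholipase that makes diacylglycerol, lost its call in 3 leave-one-out fits (highest adjusted p 0.0629 without RPMI replicate 3).

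Genes of IL-2 and STAT5 signalling fell with a median of -0.49 (camera adjusted p = 0.0169), with adjusted p = 0.405 with an estimated correlation. Of 16 members 5 fell and 0 rose, 7 and 1 adjusted over the list alone and 8 and 1 with the block. The called members Il2ra, Myc and Xcl1 are also in the effector differentiation, early gene and cytokine lists, so these lists are not separate evidence. The kinase Pim2 fell by 1.32, the feedback inhibitor Socs2 by 0.74 and Il2ra, the alpha chain of the IL-2 receptor, by 0.80 on the log2 scale, Il2ra from 1158 ± 248 to 666 ± 143 CPM (SD, n = 4). The list lost its call without RPMI replicate 3 (adjusted p = 0.0711) and with a filter of 5 CPM in 4 libraries (0.0572), and Il2ra without pEtn replicates 3 or 4 (highest adjusted p 0.0655). Of 13 p53 target and apoptosis genes 4 fell, including Zmat3 at -1.17 and Aen at -0.69, and 1 rose, the death receptor Fas at 1.21, with 7 and 1 both adjusted over the list alone and with the block. That list fell with a median of -0.47 (camera adjusted p = 0.0169), with adjusted p = 0.405 with an estimated correlation, and Cdkn1a at -1.17 lost its call with the block (adjusted p = 0.0611).

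Receptor genes split. Of 14 inhibitory receptor and exhaustion genes 3 rose, Pdcd1 by 0.99, Ctla4 by 0.96 and Entpd1 by 0.76 on the log2 scale, and the transcription factor Tox fell by 2.12 (camera adjusted p = 0.683; 3 and 2 adjusted over the list alone, 5 and 4 with the block). Pdcd1 went from 24.8 ± 7.22 to 49.2 ± 20.01 CPM (SD, n = 4). The calls of Pdcd1, Ctla4 and Entpd1 were lost in 7, 5 and 5 leave-one-out fits without the block. The highest adjusted p were 0.116 without RPMI replicate 4 for Pdcd1, and 0.0758 and 0.105 without RPMI replicate 3 for Ctla4 and Entpd1. With the block on all libraries the edgeR adjusted p of Pdcd1, Ctla4 and Entpd1 were 0.00141, 0.000204 and 0.000558. Of 12 costimulatory receptor genes 2 rose, Cd226 by 1.75 and Icos by 0.58 (camera adjusted p = 0.894; 3 higher and 1 lower adjusted over the list alone, 2 and 2 with the block). Icos lost its call without RPMI replicate 3 (adjusted p = 0.0546). Of 17 homing and adhesion genes 2 rose, Itga1 and Cxcr3, and Cd44 fell by 1.41 on the log2 scale (camera adjusted p = 0.418; 2 and 2 adjusted over the list alone, 8 and 2 with the block). Cxcr3 lost its call in 6 leave-one-out fits (highest adjusted p 0.107 without pEtn replicate 4). Of 18 naive and memory genes 3 fell, among them Il6ra at -3.99 and Id3 at -0.65, with the same count adjusted over the list alone, and the list's median of 0.09 and mean of -0.22 differed in sign (camera adjusted p = 0.547). Id3 lost its call in 6 leave-one-out fits (highest 0.117 without RPMI replicate 3), and Tcf7 stood at 57.2 ± 38.1 and 99.0 ± 49.9 CPM (SD, n = 4, edgeR adjusted p = 0.360). Of 15 effector differentiation genes 2 fell, Klrc1 from 120 ± 31.3 to 59.8 ± 14.3 CPM (SD, n = 4) and Il2ra, and 3 adjusted over the list alone (camera adjusted p = 0.953). With the block the effector list had 4 higher and 3 lower and the naive and memory list 3 higher and 6 lower.

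Mitotic genes were higher. Of 24 members 10 rose and 0 fell, 17 adjusted over the list alone and 21 with the block, with a median of 0.47 (camera adjusted p = 4.22e-07), and adjusted p = 0.577 with an estimated correlation. Cenpf, of the kinetochore, rose by 1.06, the kinase Aurka by 0.82 and the cyclin Ccnb2 by 0.63 on the log2 scale. Mki67 went from 902 ± 159 to 1364 ± 295 CPM (SD, n = 4), higher in 3 of 4 replicate numbers, and lost its call in 5 leave-one-out fits (highest adjusted p 0.130 without RPMI replicate 3). Of 23 DNA replication genes 0 rose and 1 fell, Ccne2 at -0.42, with 0 adjusted over the list alone and 2 with the block (camera adjusted p = 0.832). Ccne2 lost its call in 7 leave-one-out fits (highest adjusted p 0.117 without pEtn replicate 1).

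Ribosomal protein, serine, one-carbon and purine synthesis, and integrated stress response genes were lower. Of 28 cytosolic ribosomal protein genes 11 fell and 0 rose, 21 adjusted over the list alone and 17 with the block, with a median of -0.28 (camera adjusted p = 1.54e-07), and adjusted p = 0.405 with an estimated correlation. Rpl5 was 1.35-fold and Rps3 1.30-fold lower; these genes have many processed copies that may share reads. Of 18 serine, one-carbon and purine synthesis genes 9 fell and 0 rose, 12 adjusted over the list alone, with a median of -0.45 (camera adjusted p = 5.25e-05), and adjusted p = 0.405 with an estimated correlation. Shmt1 fell by 0.94 and the purine enzymes Ppat and Gart by 0.58 and 0.77 on the log2 scale. Of 19 integrated stress response genes 6 fell and 0 rose, 7 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.000295), and adjusted p = 0.405 with an estimated correlation. Phgdh, Psat1 and Mthfd2 are members of both this list and the serine list, so the lists are not separate evidence. The median difference of the stress response list was -0.19, -0.25, -0.59 and -0.59 in replicate numbers 1 to 4. In replicates 1 and 2 only its camera adjusted p was 0.109. Malat1 and Neat1, nuclear RNAs that serve as a sign of RNA quality, differed by medians of 1.22 and 1.28 in numbers 3 and 4. Slc7a5 and Slc3a2, which form an amino acid exchanger, fell by 0.65 and 0.53 on the log2 scale, and Sesn2 at -1.42 lost its call with the block (adjusted p = 0.0885) and in 5 leave-one-out fits (highest 0.0653 without pEtn replicate 4).

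Fatty acid oxidation genes were slightly higher, with 4 of 17 rising and 1 falling, 6 and 1 adjusted over the list alone and 8 and 1 with the block, and a median of 0.21 (camera adjusted p = 0.0128), and adjusted p = 0.405 with an estimated correlation. Cpt2 rose 1.61-fold, Cpt1a 1.45-fold and Acadl 1.43-fold, and the list's adjusted p was 0.0506 without RPMI replicate 2 and 0.125 in replicates 3 and 4 only. The 13 protein-coding genes of the mitochondrial genome had a median of 0.54 (camera adjusted p = 0.000925), and adjusted p = 0.626 with an estimated correlation. Of them 4 rose and 0 fell, 5 adjusted over the list alone, and mt-Co1 went from 4642 ± 1362 to 7916 ± 593 CPM (SD, n = 4), losing its call in 4 leave-one-out fits (highest adjusted p 0.0671 without RPMI replicate 4). The share of counts from the mitochondrial genome was 1.91% ± 0.49 in RPMI and 2.80% ± 0.13 with pEtn (SD, n = 4, exact permutation p = 0.0286, the smallest possible, and 0.286 after adjustment over 10 library measures). The median difference of the mitochondrial list was 0.30, -0.04, 1.24 and 0.93 in replicate numbers 1 to 4. That of the nuclear noncoding RNAs Malat1 and Neat1, a sign of RNA quality, was -0.06, 0.14, 1.22 and 1.28. The 3 tested markers of CD4 and regulatory T cells, Zbtb7b, Gata3 and Ikzf2, had medians of 0.48, 0.01, 0.83 and 0.95, while Cd4 stood at 0.315 and 0.126 CPM and Foxp3 at 0.190 and 0.238 CPM, before TMM scaling, too low to be tested. Of 26 nuclear-encoded respiratory chain genes 0 were called, with 0 adjusted over the list alone (camera adjusted p = 0.991).

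Interferon-stimulated genes had a median of 0.31 (camera adjusted p = 0.0151), and adjusted p = 0.943 with an estimated correlation. Of 23 members 4 rose and 0 fell, 4 and 1 adjusted over the list alone and 8 and 1 with the block. Among these, Gbp2 rose by 1.70, Zbp1 by 1.29 and Gbp3 by 1.14 on the log2 scale, Gbp2 from 133 ± 18.0 to 435 ± 153 CPM (SD, n = 4). The median difference of the list was 0.17, -0.30, 0.92 and 0.83 in replicate numbers 1 to 4. The medians of Malat1 and Neat1 in numbers 3 and 4 were 1.22 and 1.28, and those of the CD4 and regulatory T cell markers 0.83 and 0.95. The call was lost without RPMI replicate 3 (adjusted p = 0.0951) or RPMI replicate 4 (0.114). It was also lost with replicates 3 and 4 summed (0.0975, and 0.167 with the block).

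In the pathway that uses pEtn itself, Pcyt2, whose enzyme converts pEtn to CDP-ethanolamine, stood at 79.0 ± 9.60 and 78.0 ± 7.50 CPM and Etnk1, the ethanolamine kinase gene, at 233 ± 64.8 and 227 ± 28.4 CPM (SD, n = 4, edgeR adjusted p = 0.940 and 0.919). Of 20 ethanolamine and choline phospholipid genes 4 fell and 1 rose, 5 and 1 adjusted over the list alone and 8 and 2 with the block (camera adjusted p = 0.0999; fry adjusted p = 0.0238). The decarboxylase gene Pisd fell by 0.80, Ept1 by 0.64 and the kinase gene Chka by 0.55 on the log2 scale, and Pcyt1b, of the choline branch, rose by 1.21. Ept1 lost its call in 6 leave-one-out fits and Chka in 2, with highest adjusted p of 0.0939 and 0.0552, both without pEtn replicate 4. Of 22 diacylglycerol and phosphoinositide signalling genes 4 rose and 2 fell, 5 and 3 adjusted over the list alone and 7 and 6 with the block (camera adjusted p = 0.444). Dgkd, a diacylglycerol kinase gene, fell by 1.15 on the log2 scale and Pld2 rose by 0.81 (call lost in 2 leave-one-out fits, highest adjusted p 0.0544 without RPMI replicate 4), while Dgka at 0.17 and Dgkz at 0.05 had edgeR adjusted p of 0.565 and 0.827.

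The lists of glycolysis, the TCA cycle, cholesterol synthesis and fatty acid synthesis had camera adjusted p of 0.683, 0.193, 0.307 and 0.547, and those of the unfolded protein response, antioxidant and hypoxia genes 0.742, 0.832 and 0.497. Cholesterol synthesis was called with replicates 3 and 4 summed (0.0479) and in replicates 1 and 2 only (0.000444). Single called members included the lactate transporter Slc16a1 at -0.83, Hk1 at 0.65, Pcx at -1.31, Dlst at -0.58, Acss2 at 1.13, Ebp at 0.33, Gclc at -0.68 and Vegfa at -1.07 on the log2 scale. The calls of these lists were 1 higher and 1 lower in glycolysis, 2 lower in the TCA cycle, 1 higher each in cholesterol and fatty acid synthesis, 0 in the unfolded protein response, and 1 lower each in the antioxidant and hypoxia lists, with the same counts adjusted over each list alone. With the block they were 2 higher and 1 lower, 6 lower, 2 and 1, 3 and 2, 3 and 1, 4 and 4, and 1 and 3, in the same order. Ebp lost its call in 5 leave-one-out fits (highest adjusted p 0.0795 without pEtn replicate 4).

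Heat shock genes, a sign of handling stress, had 0 of 10 called, also adjusted over the list alone (camera adjusted p = 0.521), and 3 lower with the block. Malat1 stood at 14.8 ± 9.41 and 19.0 ± 2.17 CPM and Neat1 at 16.1 ± 13.9 and 21.2 ± 13.9 CPM (SD, n = 4). Of these 2 nuclear noncoding RNAs, named after their values were seen, 0 were called. Neat1 was called higher with the block (edgeR adjusted p = 0.0427). Markers of other cell types summed to 258 ± 136 and 96.1 ± 52.9 CPM, before TMM scaling, in RPMI and pEtn for B cells, of which Ighm gave 255 and 93.9. The sums were 460 ± 126 and 629 ± 146 for macrophages and monocytes, of which Ccr2, also expressed by T cells, gave 424 and 588. They were 40.1 ± 13.9 and 58.1 ± 8.90 for CD4 and regulatory T cells, 31.6 ± 17.9 and 32.8 ± 26.8 for dendritic cells, 179 ± 34.6 and 195 ± 20.5 for NK and gamma-delta T cells and 0.604 ± 0.304 and 0.484 ± 0.160 for erythroid cells and platelets (SD, n = 4). The exact permutation test of these sums gave adjusted p from 0.381 to 0.971. Its smallest possible p of 0.0286 becomes 0.286 where only 1 of the 10 measures reaches it, so a single sum could not pass. The CD4 and macrophage sums were higher with pEtn in 4 of 4 replicate numbers and the B cell sum in 0 of 4. By edgeR 1 of 3 tested markers of CD4 and regulatory T cells was called higher, Zbtb7b at 0.68 on the log2 scale (adjusted p = 0.0262, chosen after its value was seen), and 0 markers of the other lists. With the block 2 B cell markers were called lower, 2 macrophage and monocyte markers higher, 2 dendritic cell markers higher and 1 lower, and 1 NK and gamma-delta T cell marker higher and 2 lower.

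**Figure D3:**
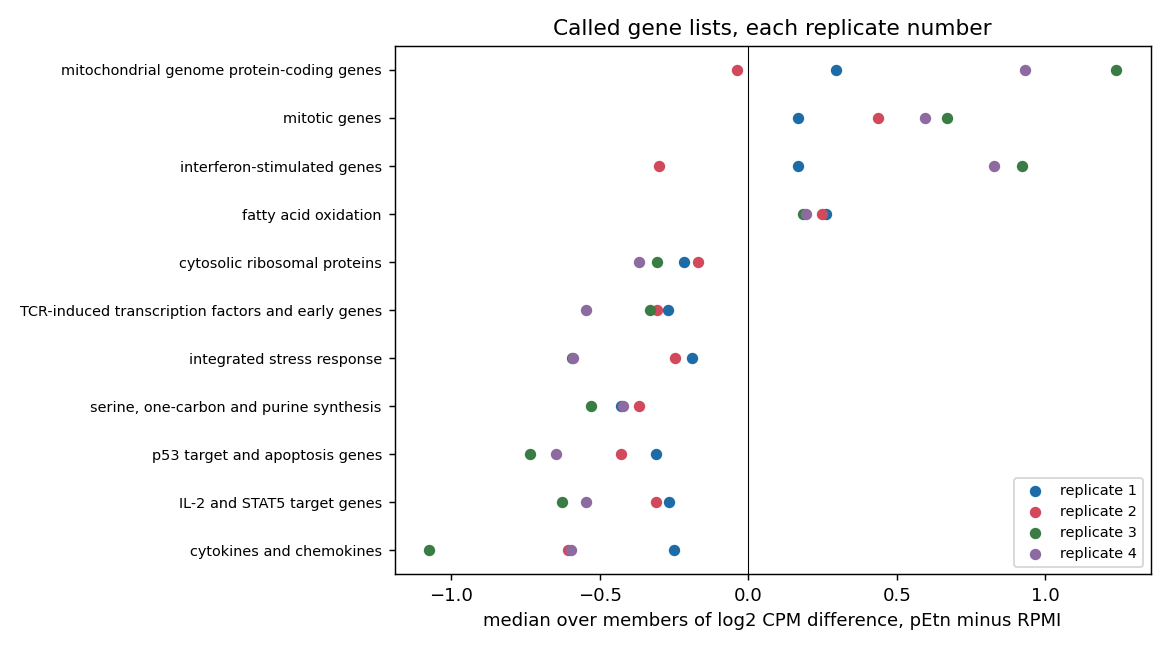
Points give the median over the members of each of the 11 called lists of the log2 CPM difference of pEtn minus RPMI (x axis), with 1 colour per replicate number. In the mitochondrial list the medians were 0.30, -0.04, 1.24 and 0.93 for numbers 1 to 4, and in fatty acid oxidation 0.26, 0.25, 0.18 and 0.19.

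Camera called 11 of the 30 tested lists, 4 up and 7 down, and the same 11 with the replicate block, but 0 with an estimated correlation, where the smallest adjusted p was 0.405. In 8 of the 11, all but the cytokine, fatty acid oxidation and serine lists, the median difference was larger in both numbers 3 and 4, where Malat1 and Neat1 differed, than in 1 and 2. In replicates 1 and 2 only, camera kept the mitotic, fatty acid oxidation, serine and ribosomal protein lists and added cholesterol synthesis. Fry called 9, losing the mitotic (adjusted p = 0.0542), mitochondrial (0.0931) and interferon lists (0.269) and adding the ethanolamine and choline list. With the block fry called 13. It then regained the mitotic list (0.0335) and lost the integrated stress response (0.0997). It added the TCA cycle (0.0306), fatty acid synthesis (0.0277), inhibitory receptor (0.0229) and homing lists (0.0344). Of 35 splits of the 8 libraries into 4 and 4, 11 called at least 11 lists, the real split included, and another split called 19, so the number of lists called with the preset correlation does not exceed what other groupings give. By Fisher's exact test the called genes were enriched in mitotic genes (10 of 24, higher), ribosomal protein genes (11 of 28, lower), serine, one-carbon and purine genes (9 of 18, lower), stress response genes (6 of 19, lower) and mitochondrial genome genes (4 of 13, higher), with adjusted p of 8.43e-06, 5.64e-05, 5.64e-05, 0.0318 and 0.0432. That test treats genes as independent, but the estimated correlation was 0.72 within the mitotic and 0.67 within the mitochondrial list. Its p-values may thus be too small, and they draw on the same 8 libraries as camera.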

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

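The tests of RPMI replicates 3 and 4, of the nuclear respiratory genes and of myeloid cells below were chosen after the results were seen. In 342 groups of 4 libraries tested, 22 held a library far from the other 3, against 17.1 that chance would give at 5% of groups. Values in this part are the gap to the nearest library as a share of the group's range.

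In pEtn replicate 1 the gap was 0.847 for the sum of CD4 and regulatory T cell markers, 0.923 for early T cell receptor genes, 0.894 for unfolded protein response genes, 0.849 for Egr2, 0.833 for Ctla4, 0.910 for Pdcd1, 0.869 for Cd28 and 0.96 for Mvk. In pEtn replicate 2 it was 0.952 for B cell markers (16.9 CPM against 120 to 125), 0.866 for Gzmf, 0.990 for Cd27, 0.842 for Tcf7 (24.8 CPM against 116 to 133) and 0.893 for Dgka. In RPMI replicate 2 it was 0.910 for cytotoxic granule genes, 0.830 for Entpd1, 0.874 for Prf1 (307 CPM against 94.3 to 121) and 0.895 for Etnk1. In RPMI replicate 1 it was 0.850 for Ifngr1, 0.941 for Hk1, 0.912 for Gzmb and 0.986 for Tcf7 (114 CPM against 37.8 to 38.9). In pEtn replicate 4 it was 0.873 for Nr4a1. Replicates 1 and 2 hold 21 of the 22 and replicates 3 and 4 the other 1. Since replicates 3 and 4 of each medium lie close together, this rule can seldom single out either of them.

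The mitochondrially encoded transcripts were higher with pEtn, with differences of 0.30, -0.04, 1.24 and 0.93 in replicate numbers 1 to 4. The nuclear-encoded respiratory chain genes had a median of 0.0009 (95% bootstrap interval -0.06 to 0.03). This interval resamples genes and not libraries, so it does not measure the spread between libraries. The medians of these genes were 0.04, 0.12, -0.08 and -0.15 in replicate numbers 1 to 4. They were not higher in numbers 3 and 4, which argues against a general rise of respiratory chain transcripts in those numbers. Offsets for GC content and length kept 108% of the median of the mitochondrial list. The low level in RPMI replicates 3 and 4 remains a candidate source, since the smaller of the differences in numbers 1 and 2 was -0.0377. The mitochondrial share of counts was nonetheless higher with pEtn in these numbers. In RPMI and pEtn it was 2.17% and 2.85% in number 1 and 2.47% and 2.81% in number 2. Malat1 and Neat1, signs of RNA quality, differed in numbers 3 and 4 as well (medians -0.06, 0.14, 1.22 and 1.28 in numbers 1 to 4), so library quality stays open. An effect of pEtn that varies between replicate numbers stays open too, and neither was tested.

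Interferon-stimulated genes were higher in replicate numbers 3 and 4 and not in 2. For macrophages, monocytes or dendritic cells, 6 of their abundant transcripts summed to 0.4 CPM in RPMI and 0.295 CPM with pEtn, a change of -0.11 CPM. This argues only against cells that carry these 6 transcripts. Among tested markers of these cells, H2-Ab1 stood at 8.83 and 17.5 CPM, Cd68 at 4.13 and 7.02 and Itgax at 1.78 and 3.31, before TMM scaling. Itgam, Ccr2 and Ctss were also higher with pEtn, and Xcr1 and Cd74 lower. A part from such cells thus stays open. Offsets for GC content and length kept 102% of the median of the called members. A difference between libraries that is unrelated to the medium may remain, since the list's median in replicates 1 and 2 only was -0.10. Library quality stays open as for the mitochondrial transcripts.

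For the lower ribosomal protein genes and higher mitotic genes, GC content and transcript length were set against an effect of the medium. With the offsets the lists kept 80.6% and 98.1% of their medians and camera adjusted p of 3.67e-06 and 4.18e-06, which argues against that bias as the whole source. An effect of pEtn stays open and was not tested apart from the difference in medium.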

How the results depend on the processing

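Fry with the block, summing replicates 3 and 4, fits on some replicate numbers, offsets for GC and length, and the block joined to other choices were chosen after seeing the data. The count of called genes was 1516 (619 higher, 897 lower) and stayed within 1.5 times under other scalings, filters, voom, TPM, RPKM, the non-robust fit and offsets (1333 to 1621). The replicate block gave 3830 (1871, 1959), quality weights 4879 (2450, 2429), a 2-fold minimum 369 (109, 260) and DESeq2 2258, with 970 higher. Replicates 3 and 4 summed gave 325 (79, 246), with the replicate block 2329 (1044 higher). Offsets with the block gave 4043 (2070, 1973). Replicates 1 and 2 only gave 32 (10, 22) and 5 lists, and replicates 3 and 4 only 5675 (2761, 2914). These fits used the same number of libraries but tested against unlike spreads. The chi-square per gene between replicates 3 and 4 was 11.2 in RPMI and 5.04 in pEtn. Between replicates 1 and 2 it was 74.1 and 51.1. The higher count thus does not show a larger effect in numbers 3 and 4, and whether the effect also differed was not tested. Leaving out 1 library gave 796 to 1638 genes, 250 to 688 higher and 542 to 950 lower, and 7 to 11 lists. Leaving out both libraries of replicate number 1, 2, 3 or 4 with the block gave 3070, 3605, 2232 and 2216 genes (1456, 1670, 1012 and 977 higher, 1614, 1935, 1220 and 1239 lower). In no alternative did a gene called both there and in all libraries change sign. The 11 lists became 0 with an estimated correlation, without and with the block. Estimating the correlation also lowers the degrees of freedom of the test, and the cause was not tested. Of 98 named called genes, 33 lost the call without at least 1 library, 54 with replicates 3 and 4 summed and 4 with the block, which added 17 named calls and changed no list call by camera. With both the sums and the block 8 lost the call, 5 of the 17 added calls remained, and the interferon list was not called (adjusted p = 0.167). Fry called 9 lists, and 13 with the block. A filter of 5 CPM in 4 libraries ended the calls of the early gene (adjusted p = 0.194), cytokine (0.446) and IL-2 lists (0.0572), and no filter added the ethanolamine and choline list (0.0421). Replicates 3 and 4 only added that list (0.0459), hypoxia (0.0154) and homing (0.0253). Leaving out number 2 with the block added homing (0.0101) and ended fatty acid oxidation and p53 (both 0.0530). Prf1, not called in all libraries, was -0.30 in replicates 3 and 4 only. In that fit 1 named gene without a call in all libraries was called with the opposite sign. The interferon list was -0.10 in replicates 1 and 2 only (camera adjusted p = 0.931, with a range over its leave-one-out fits of 0.000285 to 0.114). A sign change without a call is not counted as a reversal. The pseudocount and filter for tables without counts were not run, since the table holds counts. With independent simulated libraries at this depth, 26% of 1.5-fold changes were found, so a missing call does not show that a gene was unaffected.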

Other observations

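The lists of ribosome biogenesis factors, interferon-gamma-inducible genes and amino acid transporters, and their tests, were chosen after called genes of each kind were seen, and those genes were left out of the tests. The lists of synthetases and tissue-resident genes were written before their tests were run. Itga1, Zfp683, Itgae, Xcl1 and Cd69 of the latter had been seen and were left out, and putting the last 3 of these back was chosen after seeing the data. The p-values with an estimated correlation in this part are not adjusted over lists, unlike those of the 30 lists tested above. Unadjusted, camera with an estimated correlation gave 0.0524 for the ribosomal protein list and 0.0673 for the serine list.

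Ribosome biogenesis factors were lower with pEtn. Nop2, Nop16 and Pus7, chosen after their values were seen, fell by 1.03, 1.17 and 1.24 on the log2 scale. Of 34 further factors 31 fell and 0 rose, with a median of -0.66 and -0.79, -0.47, -0.63 and -0.67 in replicate numbers 1 to 4 (camera p = 4.25e-22, p = 0.0203 with an estimated correlation). Of 14 further amino acid and peptide transporters 4 fell and 0 rose, 9 and 1 with the block, with Slc7a6 at -0.73, Slc7a1 at -0.63, Slc1a5 at -0.54 and Slc38a1 at -0.41 (camera p = 0.00336, p = 0.0262 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, 4 of which the integrated stress response list also holds, 5 fell and 0 rose, 8 and 0 with the block, with a median of -0.23 (camera p = 0.000292, p = 0.199 with an estimated correlation).

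Interferon-gamma-inducible GTPases and antigen presentation genes were higher. Of 22 further genes 10 rose (16 with the block), among them Gbp8 at 1.03, Gbp7 at 0.79, Psmb9 at 0.73 and Tap1 at 0.58, and Irf8 fell by 0.99 on the log2 scale (camera p = 1.23e-07, p = 0.0130 with an estimated correlation). The median difference was 0.45, 0.40, 0.47 and 0.54 in replicate numbers 1 to 4, unlike the wider interferon list at 0.17, -0.30, 0.92 and 0.83. A response to interferon gamma may thus be shared by the 4 numbers, as a hypothesis found on these libraries. There it was tested only as a shift of a gene list, and interferon gamma as the cause was not tested. The Gbp and H2 genes have close copies that may share reads.

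Tissue-resident memory genes other than Itga1 and Zfp683 did not move in 1 direction. Of 14 genes, 4 of which lists of the report also hold (Nr4a2, Cd101, Cxcr6 and Hspa1a), 8 had changes above 0 and 6 below, and Inpp4b, which fell by 0.61 on the log2 scale, was the 1 called by edgeR. With the block 3 were called higher (P2rx7, Cxcr6 and Qpct) and 3 lower (Inpp4b, Nr4a2 and Ahr). The 3 left out had changes below 0, Xcl1 at -1.13 (adjusted p = 0.0460), Itgae at -2.22 (0.0627, and 0.00176 with the block) and Cd69 at -0.26 (0.606). With them the median went from 0.05 to -0.16 and the camera p from 0.508 to 0.170 (p = 0.318 with an estimated correlation). For the 14 the camera test of limma gave an adjusted p of 0.508 over the 5 lists of this part, against 2.12e-21 for ribosome biogenesis factors, 3.08e-07 for interferon-gamma-inducible genes, 0.000486 for synthetases and 0.0042 for transporters.

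Of the 35 splits of the 8 libraries into 4 and 4, the real split called 1516 genes and 1 split, the real one, called as many; the highest other gave 978. Over these 35 splits chance could be excluded as the source of the gene count only if any library could have stood in either group. The pairing by number and the closeness of replicates 3 and 4 go against this condition, so chance is not excluded. That other split sets replicates 1 and 2 against 3 and 4, which points to a structure of the libraries. The replicate numbers pair the libraries, and only 8 splits part all 4 pairs, as the real one does. Among these the highest other called 0 genes, and 8 splits are too few for a share under 0.05. For lists chance cannot be excluded, since 11 of the 35 splits called at least the 11 lists of the real split and the highest other called 19, or 14 among splits that part all pairs. The camera p-values with the preset correlation in this part carry the same limit.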
